A study of Mus musculus with 5 samples.

How the data were processed

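Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against Gata6 was carried out on the pancreas of wild-type C57BL/6 mice. Per the labels' protocols, the tissue was minced, crosslinked, homogenized and sonicated before immunoprecipitation, and DNA fragments were size selected and sequenced on an Illumina Genome Analyzer IIx. There were 4 Gata6 libraries, 2 from mice aged 5 weeks and 2 from mice aged 14 weeks, and 1 input library, which per the labels held DNA from all input replicates in equal amounts. The samples were grouped by their titles into Gata6 ChIP and input.

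The authors deposited 1 peak list for the whole series, with a chromosome, a start and an end per line and no header. Positions are base pairs of the mouse genome build mm9, per the submitters' processing notes. The list uses the names of sequence parts (1_random, 8_random and Un_random) that mm9 holds. CASAVA 1.8 and BWA 0.5.9-r16 are named in the submitters' processing notes, without their role. The name of the deposited list holds the abbreviation FDR followed by the digit 1, with no explanation. The peak caller, its settings, the threshold and whether peaks were called on pooled or separate libraries are not given in the sources used here. The list was therefore treated as a single pooled result of the 4 Gata6 libraries. It holds no score, height, p-value or value per library. Sequencing depth is unknown, and neither the spread between animals nor a difference between ages could be computed. Where the caller's power varied with local coverage or mappability, the list would carry that variation, and nothing in it allows a correction.

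Starts were read as 0-based and are printed 1-based. The midpoint of each peak stood for its position. The 19 autosomes and X were used for all tests. Chromosome lengths of mm9 came from the R package GenomeInfoDb 1.38.1 and cytogenetic bands of mm9 from circlize 0.4.16, read with R 4.3.3. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The gene table at hand describes another build (GRCm38.p6). Only its number of protein-coding genes per chromosome was used, and none of its positions. No mm9 gene annotation or sequence was used here, so the planned comparisons of peaks with genes, with 17 gene lists and with 19 sequence motifs were not run. Peaks were therefore named by position under the rule set for that case, which takes the 10 widest peaks and the 5 windows of 50 kb with the most peaks. Windows started at multiples of 50 kb, and ties were resolved in chromosome order.

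Peaks per chromosome were compared with numbers expected from chromosome length by a chi-square statistic with a p-value from 100000 multinomial draws. Each chromosome was tested with an exact two-sided binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes and a threshold of 0.05. Clustering was measured as the share of peaks with another midpoint within 10 kb, against 100 random placements that kept the number of peaks per chromosome. The smallest p this allows is 0.0099. The share of peaks in bands of one stain was compared with 10000 rotations, in which all peaks of a chromosome were moved around it together by a random offset. Intervals are exact 95% Poisson intervals. They cover counting error only and treat peaks as independent, which the clustering of peaks contradicts, so they are too narrow. The binomial and chi-square p-values rest on the same independence and are too small. Permutation p-values of peak width also treat peaks as independent. All tests treat peaks as units of 1 list and say nothing about variation between animals.

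The tests were also run on simulated data with 7733 peaks. Among 50 simulated sets with no effect, the chi-square test passed the threshold in 2. The clustered share lay above all 19 placements drawn per set in 3, and the test of the darkest bands passed in 2. Fewer draws and rotations were used than for the list itself, and the test of light bands was not simulated. Peaks of these sets were placed evenly and independently, so the sets do not give the rate of false calls for a clustered list. In all 50 sets with X at 0.2 and chromosome 11 at 1.5 times their length share and 20% of peaks set in close pairs, X was called low, chromosome 11 was called high and clustering was found. Peaks removed from the darkest bands at a rate of 40% were detected in all 50 sets.

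Choices made before the data were examined were the tests of chromosomes and clusters, the 10 kb limit and its alternatives (1 and 50 kb), restriction to the wider 3868 peaks, merging of peaks within 500 bp, and counting peaks within 10 kb once. Chosen after seeing the list were the gene-number expectation, the tests on autosomes alone, without the first 3 Mb of each chromosome and on the first 3868 lines of the list, the placements within bands and within 1 Mb bins, the merging of peaks with edges within 2 kb, and all analyses of bands, gene density, gaps and line order. No column of per-sample values was set aside, since the list has none.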

Results

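Gata6 is a zinc-finger transcription factor that binds GATA sequence motifs and takes part in the development and upkeep of the exocrine pancreas. The series asked where Gata6 binds the genome of the mouse pancreas. Gata6 ChIP-seq was performed on 4 pancreas libraries of wild-type C57BL/6 mice, 2 from mice aged 5 weeks and 2 from mice aged 14 weeks, with 1 library of pooled input DNA as the background sample. The processed result was 1 list of 7737 peaks on mm9. As it gives positions only, with no value per library, there was no replicate spread, the sequencing depth was unknown, and the 2 ages could not be compared. Tests below treat each peak as a unit.

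Gata6 peaks were short and spread over all autosomes. The 7737 peaks had a median width of 728 bp, with an interquartile range of 533 to 996 bp and extremes of 190 and 6367 bp, and 5827 of them (75.3%) were narrower than 1 kb. Together the peaks covered 6302 kb. On the 19 autosomes and X this was 0.239% of the sequence, at a mean density of 2.93 peaks per Mb. No peaks overlapped or touched each other. No peak was listed on chromosome Y or on the mitochondrial genome.

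The widest peak lay on chromosome 2 at 28414568 to 28420934 in band qA3 and spanned 6367 bp. The second, of 6038 bp, lay on chromosome 17 at 39979838 to 39985875 in band qB1. The nearest other peak was 2903 kb away, and without mm9 sequence or repeat annotation it was not checked whether this wide, isolated peak lies on repeated sequence, where reads from several copies can pile up. The third, of 3995 bp, lay on chromosome 4 at 141371632 to 141375626 in band qE1. Chromosome 15 held 3 of the 10 widest peaks. A pair in band qE1 at 78673497 to 78677208 and 78679982 to 78683375 measured 3712 and 3394 bp, and a peak of 3497 bp in band qF1 lay at 100510307 to 100513803. Chromosome 5 band qF held a peak of 3839 bp at 108151954 to 108155792 and, far from it, one of 3600 bp at 123584460 to 123588059. The remaining ones were a peak of 3628 bp on chromosome 9 at 44292697 to 44296324 and one of 3568 bp on chromosome 11 at 69230602 to 69234169. Among these 10 peaks, 6 had another peak within 10 kb.

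The first comparison asked whether Gata6 peaks were spread over the chromosomes in proportion to length. Chromosome 11 carried the highest density, 5.33 peaks per Mb (95% interval 4.92 to 5.75), with 649 peaks against 357 expected. Chromosome 19 followed with 4.63 per Mb (4.11 to 5.20), 284 peaks against 179.8 expected. Chromosome X had the lowest density. It held 53 peaks against 488 expected, or 0.318 per Mb (0.238 to 0.416), where the 19 autosomes ranged from 2.17 per Mb on chromosome 14 to 5.33 on chromosome 11. The pooled autosomal density of 3.11 per Mb was 9.77 times that of X.

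Across the 20 chromosomes the peaks did not follow length (chi-square statistic 819 with 19 degrees of freedom, p = 1e-05 from multinomial draws of independent peaks, the smallest the 100000 draws can give). In the exact binomial test, 8 chromosomes lay above the length expectation (4, 5, 7, 9, 11, 15, 17 and 19) and 5 below it (1, 3, 14, 16 and X). The adjusted p was 2.96e-45 for chromosome 11, 2.23e-12 for chromosome 19 and 8.41e-144 for X, while the other called chromosomes had ratios of observed to expected peaks between 0.741 and 1.23. On autosomes alone, with the expected numbers taken without X, 4 of the 8 remained above expectation (4, 11, 17 and 19), chromosomes 5, 7, 9 and 15 did not pass, and 6 and 13 passed below it. Chromosome 15 did not pass with peaks within 10 kb counted once (ratio 1.06, adjusted p = 0.47, range over its alternatives 8.6e-05 to 0.47, exact binomial test), chromosomes 1, 7, 9, 15 and 16 did not pass in the first 3868 lines of the list, and 16 did not among the wider 3868 peaks.

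**Figure D1:**
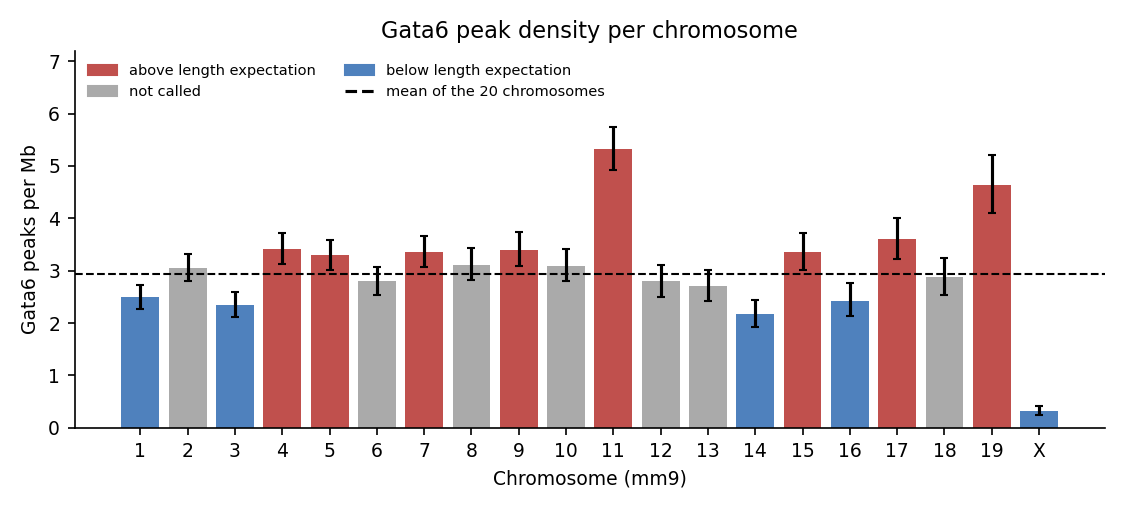
Gata6 peaks per Mb (y axis) on each mm9 chromosome (x axis), with exact 95% Poisson intervals as error bars. Red and blue bars passed the exact binomial test above and below the length expectation, and grey bars did not. The dashed line is the mean over the pooled length of the 20 chromosomes, 2.93 per Mb. X stands at 0.318 per Mb, below every autosome.

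Gene number, an expectation chosen after the list was seen, gave a different order of the autosomes, and X was again the lowest. Set against the number of protein-coding genes on each chromosome, the autosomes together had 37.2 peaks per 100 genes, from 25.3 on chromosome 7 (95% interval 23.1 to 27.6) to 51.1 on chromosome 18 (45.1 to 57.7). Chromosome 12 had 49.9 (44.8 to 55.5) and chromosome 11 had 40.3 (37.3 to 43.6). X had 5.49 peaks per 100 genes (4.11 to 7.18). With this expectation, among the chromosomes called by length, the ratios of 1 and 3 turned from below to above 1. Those of 7, 9 and 17 turned from above to below 1. In the new direction, 1 and 7 passed the exact binomial test. Among chromosomes not called by length, the ratios of 6, 12, 13 and 18 turned above 1 and that of 2 below it. Chromosomes 14, 16 and 19 no longer passed, while 10, 12 and 18 newly passed above expectation (ratios 1.12, 1.40 and 1.43) and chromosome 2 below it (0.873). Chromosomes 4, 5, 11 and 15 were called above expectation and X below it under both expectations. By gene number the ratios of 4, 5, 11 and 15 were 1.12, 1.11, 1.13 and 1.25, while chromosome 11 had 1.82 by length. Both expectations included X, whose few peaks lowered the expected numbers of all autosomes. By length without X, 5 and 15 did not pass, and the gene-number expectation was not run without X.

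**Figure D2:**
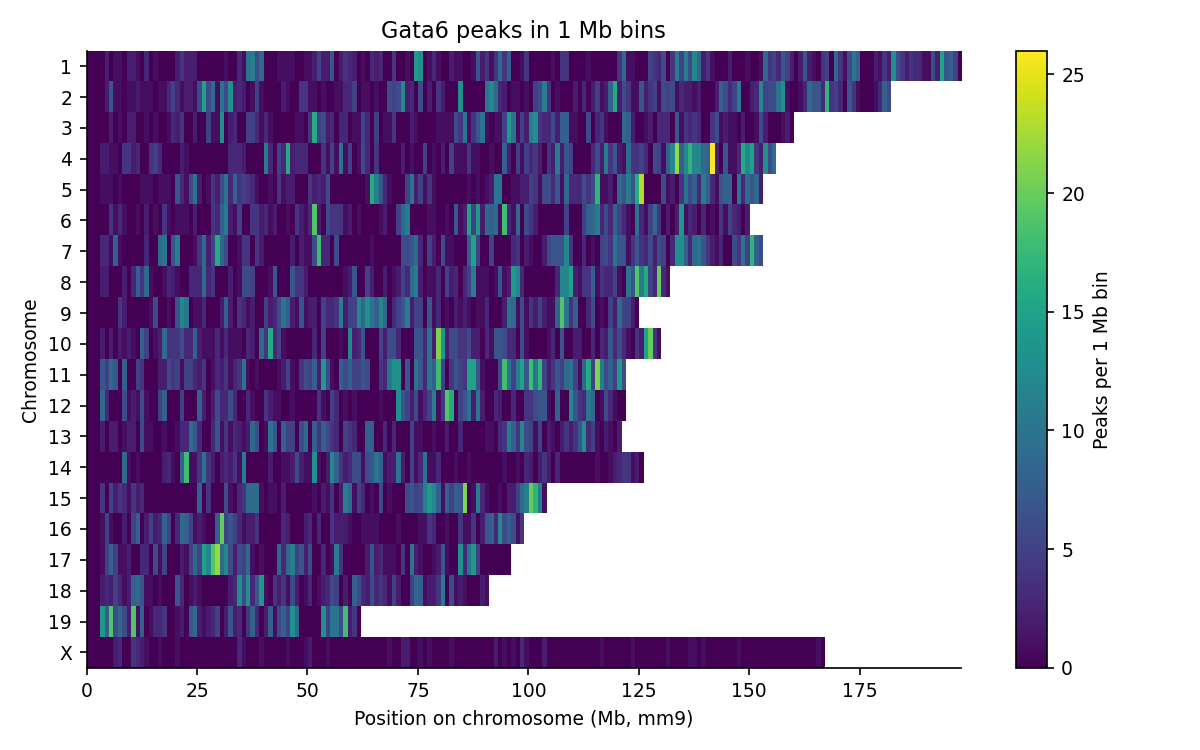
Number of Gata6 peaks per 1 Mb bin (colour) along each mm9 chromosome (x axis, Mb; y axis, chromosome). The fullest bin, on chromosome 4 between 141000001 and 142000000, held 26 peaks, and 132 of the 167 bins of X held none.

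The second comparison asked whether peaks lay closer together than random placement allows. Gata6 peaks came in local groups. In total 2233 of 7733 peaks (28.9%) had another peak midpoint within 10 kb, against 6.19% ± 0.373 (SD over 100 random placements) and at most 7.27% in any placement, a 4.66-fold excess (p = 0.0099, one-sided permutation test, the smallest 100 placements can give). When random placements kept the number of peaks in each 1 Mb bin, the share was 12.8% ± 0.507 (SD) and the excess 2.26-fold. The median distance to the nearest peak was 31.4 kb, with an interquartile range of 8.03 to 96.9 kb.

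Joining peaks whose midpoints followed each other within 10 kb gave 941 groups, of which 718 were pairs and 223 held 3 or more peaks. Random placements gave 8.09 groups of 3 or more on average and at most 20, and placements that kept 1 Mb bins gave 41.2 on average and at most 55. The largest group, 13 peaks over 25.2 kb, lay on chromosome 15 at 100503931 to 100529135. No random placement joined more than 5 peaks and none that kept 1 Mb bins joined more than 6. Most gaps between neighbours in this group were shorter than the peaks. Numbers and sizes of groups were not recomputed with peaks of nearby edges merged, so a region split into several peaks can count as a group. Peaks with a neighbour within 10 kb were wider than the others, with means of 881 bp (SD 468, n = 2233) and 788 bp (SD 393, n = 5500), a difference of 93.3 bp (two-sided permutation p = 1e-05).

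**Figure D3:**
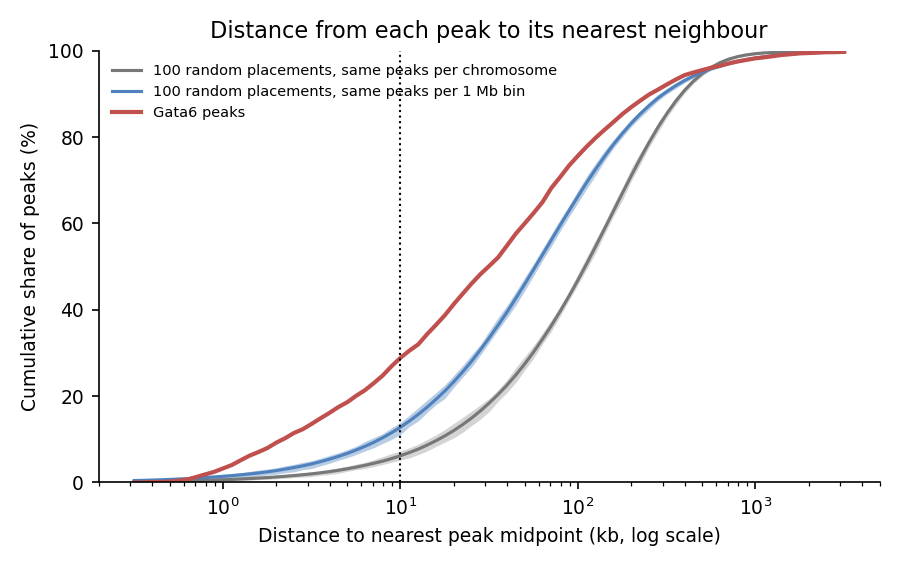
Cumulative share of peaks (y axis, %) by distance to the nearest other peak midpoint (x axis, kb, log scale) for the Gata6 list, for 100 random placements with the same peaks per chromosome and for 100 with the same peaks per 1 Mb bin (lines, means; bands, lowest to highest). At 10 kb (dotted line) the shares were 28.9%, 6.19% and 12.8%.

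The 5 fixed windows of 50 kb with the most peaks lay on chromosomes 15, 4 and 8. The window on chromosome 15 at 100500001 to 100550000 in band qF1 held 13 peaks that covered 19171 bp, the widest of them 3497 bp. On chromosome 4 band qE1, the adjoining windows at 141350001 to 141400000 and 141400001 to 141450000 held 9 and 7 peaks and covered 13934 and 6784 bp. The window on chromosome 4 at 136950001 to 137000000 in band qD3 held 8 peaks, none wider than 1384 bp. The window on chromosome 8 at 124800001 to 124850000 in band qE1 also held 8 peaks, the widest of 2740 bp. A count of 7 was shared by 3 windows, and 4339 of the windows with a peak held a single one. With windows free to start at any peak, the region of chromosome 4 around 141373628 came first with 14 peaks, followed by that of chromosome 15 with 13.

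**Figure D4:**
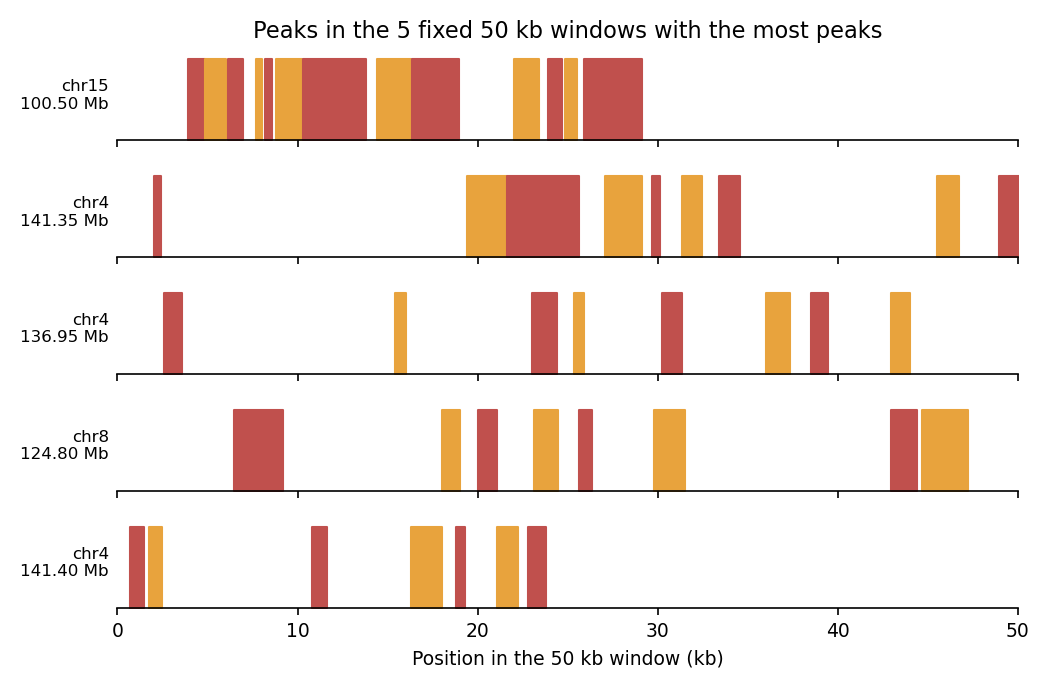
Peaks (coloured blocks, drawn to scale, neighbouring peaks in alternating colours) along the 5 fixed 50 kb windows with the most peaks (x axis, kb from the window's start, given at the left in Mb of mm9). The window on chromosome 15 holds 13 peaks, with gaps between neighbours that are mostly shorter than the peaks, and those on chromosome 8 and at 136950001 on chromosome 4 hold 8 each.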

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

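Outside the comparisons of chromosomes and clusters, the list held 4 peaks on sequence that mm9 does not place on a chromosome: 1 on 1_random at 412225 to 412809, 1 on 8_random at 772015 to 772899, and 2 on Un_random at 2747625 to 2749117 and 3647508 to 3647913. Whether 4 is many or few for the length of this sequence was not tested.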

How the results depend on the processing

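The expectation by gene number, autosomes alone, the first 3868 lines, placements within bands or 1 Mb bins, omission of the first 3 Mb and all band tests were chosen only after the data were seen. The uneven spread over chromosomes stayed past the threshold under every alternative run. The deficit of X, the clustering and both band results did so too and kept their direction. The chi-square statistic ranged from 382 to 832 and the ratio of X from 0.0614 to 0.153. The clustering excess ranged from 2.19-fold, with the 50 kb limit and placements that kept peaks per chromosome, to 7.10-fold, among the wider 3868 peaks. There the observed share was 23.7%, and fewer placed peaks lowered the random share to 3.33%. With 1 Mb bins kept, a limit near 50 kb, not among these alternatives, gave 60.0% against a mean of 46.0%. Merging peaks with edges within 2 kb, tested apart from these alternatives, left 1.65-fold over placements that kept 1 Mb bins. The share in light bands ranged from 1.15 to 1.19 times and that in the darkest bands from 0.584 to 0.700 times the length expectation. Keeping the wider peaks left 3868 by construction. It called 8 chromosomes below expectation instead of 5. The gene-number expectation called 3 below, autosomes alone called 4 above instead of 8, and the first 3868 lines called 5 above and 3 below. Among chromosomes called by length, 5 ratios reversed under the gene-number expectation, to 1.14 for chromosome 1, 1.06 for chromosome 3, 0.707 for chromosome 7, 0.983 for chromosome 9 and 0.906 for chromosome 17. The expectation itself changed there, and autosomes alone lack X. The cause of the other changes was not tested. Among 118 alternative values, 93 were classed as unchanged. For ratios and tests this meant the same side and the same call, and for counts and widths a change within a set tolerance. Another 14 ratios of single chromosomes kept their side but no longer passed, 6 counts moved past the tolerance and 5 ratios reversed. Only ratios of chromosomes called by length were counted. Not run for lack of mm9 sequence or annotation were lengths without assembly gaps and all alternatives for positions against genes, motifs and gene lists, and for lack of a score those on peak scores. Leaving out a library was not possible with a pooled list. Unknown depth leaves open how many weaker sites were missed. No paired analysis was possible because the list carries no values per library.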

Other observations

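The tests of bands, gene density, stretches without peaks, peak width on X, a single copy of X, merged regions and line order were chosen only after the result was seen. Gata6 peaks were sparse in the darkest cytogenetic bands, which are in general late replicating and poor in genes. These bands (stain class gpos100) held 1613 peaks, 1.95 per Mb (95% interval 1.85 to 2.04), against 3.44 (3.33 to 3.55) in light bands, 3.51 (3.33 to 3.69) in the palest stained class (gpos33) and 3.01 (2.81 to 3.21) in gpos66. They took 20.9% of the peaks with 31.4% of the length, fewer than in any of 10000 rotations (lowest 24.4%, permutation p = 0.0001, the smallest possible, one-sided). On every chromosome the first band was of this class, and no peak lay before 3.12 Mb, which lowers its density. Without the first 3 Mb of each chromosome, the share of the darkest bands was 0.700 times the length expectation instead of 0.664 (permutation p = 0.0001, one-sided). Light bands took 48.0% of the peaks with 40.9% of the length (highest rotation 47.6%, permutation p = 0.0001, one-sided). Light bands were denser than the others on 16 of 20 chromosomes and not on 12, 15, 19 and X.

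The densest bands past the exact binomial threshold were qD3 on chromosome 4 (133192649 to 140830936), with 95 peaks or 12.4 per Mb, and qF2 on chromosome 15 (100759425 to 101671274), with 11 peaks or 12.1 per Mb. Next came qD2 on chromosome 6, with 17 peaks or 11.6 per Mb, and qA3.3 on chromosome 17 (21851526 to 31466196), with 105 peaks or 10.9 per Mb. Of 395 bands, 86 passed above the length expectation and 111 below it, with Benjamini-Hochberg adjustment over all bands. The longest stretch without a peak, 18.1 Mb, lay on X at 147531219 to 165658025. The longest on an autosome lay on chromosome 15 at 12125353 to 25562418, measured 13.4 Mb and took in the whole light band qA2. Of 52 stretches longer than 5 Mb between neighbouring peaks, 11 were on X. Across the 19 autosomes, peaks per Mb rose with protein-coding genes per Mb (Pearson r = 0.79, permutation p = 6e-05; Spearman rho = 0.81, permutation p = 6e-05; 1 relation computed). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.81 over 17 chromosomes (permutation p = 3e-05).

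X held few Gata6 peaks, and 3 explanations were set against that. Fewer genes on X would leave its peaks per gene in the autosomal range, but X had 5.49 per 100 genes (interval up to 7.18) and the lowest autosome 25.3. More dark bands would leave the light bands of X at autosomal density, but these had 0.226 peaks per Mb (up to 0.379) and the lowest autosome 2.47. A single copy of X, as in males, with peak numbers proportional to copies would give at least 0.5 of the autosomal density, but the ratio was 0.102 (up to 0.134); a fixed calling threshold could remove more than that share, which stays open, as do repeats that reads cannot be assigned to, since the labels give no sex and the list no heights, and no biological explanation was tested. X peaks were also narrower, with means of 614 bp (SD 222, n = 53) against 816 bp (SD 419, n = 7680; two-sided permutation p = 0.0014).

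Peaks lay close together, and 2 technical explanations were weighed. Uneven density at the scale of 1 Mb lowered the excess of neighbours within 10 kb from 4.66-fold to 2.26-fold but did not remove it, with 0 of 100 placements as high. Enriched regions split into several peaks would place the excess within 2 kb, where it was 3.41-fold over placements that kept 1 Mb bins (9.28% against 2.72%), yet peaks with the nearest midpoint 2 to 10 kb away were also 1.95-fold more frequent, and without the 276 of these 1515 peaks that had edges within 2 kb of a neighbour, the remaining 1239 of 7733 still exceeded the highest share of any placement, 11.4%. After all peaks with edges within 2 kb were merged, 1369 of the 7200 regions still had a neighbour within 10 kb, 1.65 times the mean share of 11.5% in placements that kept 1 Mb bins (0 of 100 as high), which argues against splits of up to 2 kb as the whole cause. Splits with wider gaps and copy-number differences between the animals and the reference stay open, and no biological explanation was tested.

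The line order of the list may carry a ranking that the list does not print. The list consisted of 94 runs, each sorted by chromosome name and start, with 93 breaks between them, where 100 random orders of the lines gave 3815 to 3951. Line number fell with width (Spearman rho = -0.20 across peaks, two-sided permutation p = 1e-05), and rho stayed negative over the middle 50% of the lines (rho = -0.13, two-sided permutation p = 1e-05). Over 4 successive parts of the list, of 1934 or 1935 lines each, the median width was 785, 789, 717 and 622 bp. What the order ranks stays open, as the list prints no score, and no biological explanation was tested.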
